A study of Mus musculus with 12 samples.

How the data were processed

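RNA was measured in 12 libraries of regulatory T cells (Tregs) sorted from the omentum, the fatty fold of the abdominal lining, of tumour-bearing female mice. Per the labels' protocols, mice aged 8 to 12 weeks received cells of EG7.1.15, a thymoma line, in the peritoneal cavity, and the cells were taken on day 15. The sort gate was live CD45.2+ CD4+ CD25+ Foxp3-GFP+ and either positive or negative for ST2, the receptor for IL-33 that the gene Il1rl1 encodes. Mice were conventional and untreated or were treated with arginine. The arginine dose and route are not given in the sources used here, and neither is a sort day or a batch. The deposited files number all libraries of untreated mice in one series and all those of arginine-treated mice in another. If these series are library or sequencing batches, batch and treatment cannot be told apart in any arginine effect. The 2 gates and the 2 treatments make 4 groups of 3 libraries. Per the labels' protocols, total RNA was extracted with the Quick-RNA MicroPrep kit, amplified with SMART-seq v4 chemistry and made into libraries with Nextera XT from 200 pg of cDNA. This chemistry does not keep the strand, so reads of genes that overlap on opposite strands cannot be told apart.

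The deposited files hold the authors' raw counts, one file per library, with reads counted per gene symbol and no normalization. The submitters' processing notes name Trim Galore 0.44, TopHat2 2.1.1, SAMtools 1.9, HTSeq 0.6.1, DESeq2 1.20.0 and the mm10 genome build. The gene annotation and the strand setting used for counting are not given in the sources used here. Each file lists 40840 genes and 5 HTSeq summary lines, among them the reads that fall in no annotated feature. The no-feature share reported here is those reads as a percent of the counts of genes, ambiguous reads and no-feature reads together. Of the mitochondrial genome the files list only the ribosomal RNAs mt-Rnr1 and mt-Rnr2. Positions come from GENCODE M21 on the same build (GRCm38), in which 30153 of the gene symbols were found.

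Counts of genes were analysed in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16 with the groups as its design, which left 15476 genes. Library sizes were normalised by the trimmed mean of M values (TMM). A quasi-likelihood negative binomial model of edgeR with a mean per group was fitted to all 12 libraries, and each comparison was a contrast of its coefficients. The comparisons were ST2-positive against ST2-negative cells in untreated mice, the same in arginine-treated mice, arginine-treated against untreated mice in ST2-negative cells, the same in ST2-positive cells, and the interaction, the arginine effect in ST2-positive cells minus that in ST2-negative cells. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are log2 values with their standard error (SE). Unless stated otherwise, levels are TMM-normalised CPM (counts scaled to a fixed library total), given as mean ± SD of a group's 3 libraries. Logs of CPM used a prior count of 2.

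The libraries held 2924690 to 5299932 counts in genes. A floor of 3 counts in a library corresponds to 0.566 to 1.03 CPM, and floors cover counting error only, since the reads carry no molecular identifiers. The fits were tested on simulated counts with the depth and dispersion of these libraries. For each comparison 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold, far fewer than the genes called between the gates. Changed genes that the filter removed counted as missed. The share recovered depends on how many genes change, so these shares do not give the power of the real comparisons. Of genes changed 2-fold, 64.2%, 58.2%, 52.2%, 46.3% and 37.3% were recovered in the 5 comparisons in the order above. Of genes changed 4-fold, 77.3%, 81.8%, 83.3%, 78.8% and 63.6% were recovered. Calls on unchanged genes made up 8.33%, 8.33%, 7.14%, 8.04% and 7.5% of the calls.

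Before the data were examined, 30 gene lists and the rule for named genes were fixed. Named genes are the sort markers (Il1rl1, Foxp3, Cd4, Il2ra, Ptprc), the genes Pparg, Gata3, Klrg1, Areg, Arg1, Odc1 and Slc7a1, up to 10 genes each way with the largest log2 fold change, and up to 4 passing members of each list by p. The genes of the third part had to pass the test, average at least 10 CPM and have all 3 libraries of a group above all 3 of the other. Predicted genes, clones and receptor segments were left out of it, and some list members are left out of the text for space. Il1r2 in the comparison of gates was named after its values were seen, as the single member of its list with the opposite sign. Lists were tested with camera of limma 3.58.1 on voom values, with an inter-gene correlation preset at 0.01 and p-values adjusted over the 30 lists. Camera compares a list with all other genes. Some lists share members, so their results are not independent of each other. In another list too were 10 of 22 visceral adipose tissue Treg genes and 6 of 17 suppressive effector genes. The same held for 4 of 12 Th2-associated genes and 11 of 23 chemokine receptor and adhesion genes. The alternatives were an estimated correlation for each list and fry, a rotation test.

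The other alternatives were DESeq2 size factors, no filter on low counts, at least 5 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, a fit on only the 6 libraries compared, a block on replicate number, and leaving out each library in turn. A covariate for the no-feature share, and camera with libraries left out for 4 of the lists, were added after the data had been seen. Correlations used permutation tests, and group measures and list scores used exact permutation tests, all of them two-sided. The p-values measure the spread between these libraries, since the labels do not say whether the libraries of a group come from separate animals. No library was left out.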

Results

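Gene expression was measured by RNA sequencing in Tregs sorted from the omentum of tumour-bearing mice, as ST2-positive and ST2-negative cells from untreated and from arginine-treated mice, with 3 libraries in each of the 4 groups. The ST2-negative libraries of untreated mice held 4759697, 4533464 and 4684407 counts in genes, and those of arginine-treated mice 3641418, 4291342 and 4054005. The ST2-positive libraries of untreated mice held 5299932, 3907709 and 2924690 counts, and those of arginine-treated mice 3374928, 4007400 and 3456481. Correlations of log2 CPM between libraries of a group ranged from 0.959 to 0.974.

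Il1rl1, which encodes ST2 and checks the sort, separated the gates in every library. Its level was 164 ± 2.66 CPM in ST2-negative and 1353 ± 159 CPM in ST2-positive cells of untreated mice, and 338 ± 26.3 and 1639 ± 103 CPM in those of arginine-treated mice (SD, n = 3). Il1rl1 lies on chromosome 1 at 40429570 to 40465415. Foxp3, the lineage factor of Tregs on chromosome X at 7573644 to 7595245, was present in all groups at 89.5 ± 2.23, 109 ± 5.43, 120 ± 12.2 and 125 ± 8.95 CPM, in the order ST2-negative untreated, ST2-negative arginine, ST2-positive untreated and ST2-positive arginine. In untreated mice Foxp3 was 0.43 higher (log2, SE 0.106) in ST2-positive cells, with an adjusted p of 0.00679 by edgeR that became 0.0656 without ST2-positive untreated replicate 1. Il2ra, the CD25 chain of the IL-2 receptor, was higher in ST2-positive cells by 0.93 in untreated and 0.78 in arginine-treated mice (adjusted p = 1.65e-07 and 3.26e-06, edgeR). Cd4 and Ptprc (CD45) passed the test in none of the 5 comparisons, with edgeR adjusted p of at least 0.173.

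**Figure D1:**
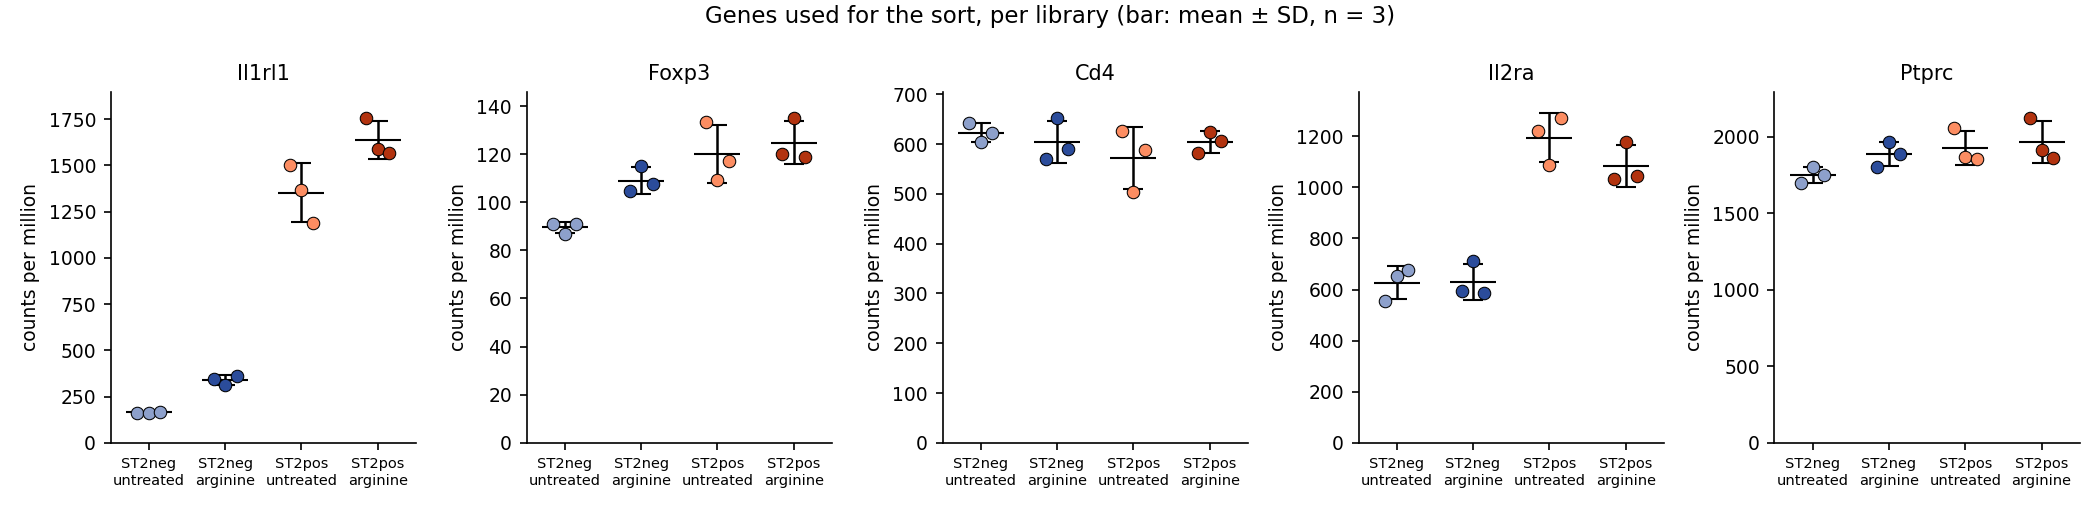
Expression in CPM (vertical axis) of the 5 genes used for the sort, by group (horizontal axis); points are libraries, and bars show mean ± SD (n = 3). Il1rl1 separates the ST2-positive from the ST2-negative libraries, and its mean is 338 CPM in ST2-negative cells of arginine-treated mice against 164 CPM in those of untreated mice.

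The libraries differed in the share of reads that fell in no annotated feature. This share was 33.3% ± 1.17 in ST2-negative and 47.3% ± 5.64 in ST2-positive cells of untreated mice, without overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). In arginine-treated mice it was 40.3% ± 8.35 in ST2-negative and 44.4% ± 3.78 in ST2-positive cells (exact permutation p = 0.5). ST2-negative arginine replicate 2 had 30.6%, against 45.3% and 44.8% in replicates 1 and 3. Principal component 1 held 37.4% of the variance of log2 CPM, and that library scored 57.7 on it, against -2.99 and -3.31 for the other 2 of its group. Between 24402 and 30135 genes had at least 1 count in a library.

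**Figure D2:**
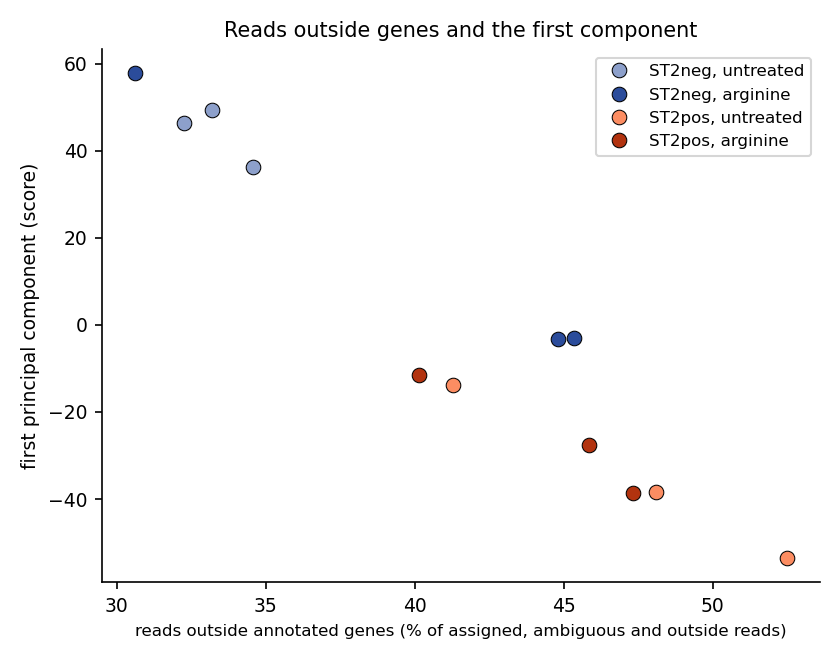
Score on principal component 1 of log2 CPM (vertical axis) against the percent of reads in no annotated feature (horizontal axis), with a point for each of the 12 libraries coloured by group. ST2-negative arginine replicate 2, at 30.6%, lies beyond the ST2-negative libraries of untreated mice on both axes and apart from the other 2 of its group.

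The first comparison asked how ST2-positive omental Tregs differ from ST2-negative ones in untreated mice. ST2-positive cells carried more RNA of several genes known from visceral fat Tregs. Klrg1, a surface marker of effector Tregs, rose from 414 ± 52.9 to 1466 ± 63.9 CPM. Gata3, a transcription factor of type 2 immunity, rose from 626 ± 48.3 to 1257 ± 98.1 CPM, and Areg, a growth factor for tissue repair, from 408 ± 5.47 to 886 ± 73.6 CPM. Pparg, the fat-tissue transcription factor, was 0.86 higher (log2, SE 0.155). Ccr7, the receptor that guides cells to lymph nodes (chromosome 11 at 99144196 to 99155077), was at 569 ± 65.8 CPM in ST2-negative and 67.5 ± 7.14 CPM in ST2-positive cells.

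Secreted mediators and receptors were among the named genes with the largest rises in ST2-positive cells of untreated mice. Il5, the eosinophil growth factor (chromosome 11 at 53720794 to 53725106), was at 45.3 ± 3.87 CPM in ST2-positive and 2.09 ± 2.19 CPM in ST2-negative cells, where it was near the detection floor. The chemokine receptor genes Ccr1 and Ccr3 were 2.98 and 2.51 higher (log2, SE 0.146 and 0.136). Nmur1, the receptor for the nerve peptide neuromedin U, was 2.88 higher (SE 0.296), and Calca, which encodes calcitonin gene-related peptide, 2.64 higher (SE 0.18). Ctla2a, an inhibitor of cysteine proteases, rose by 2.57 (SE 0.121). Falls included Cxcr5, the receptor for B cell follicles, at -4.05 (SE 0.492), the cytotoxic granule gene Nkg7 at -2.49 (SE 0.148), the tetraspanin Cd9 at -2.31 (SE 0.245) and the phosphatase Ptpn5 at -2.25 (SE 0.149). Xcl1, a chemokine of lymphocytes, had 25.3 ± 12.2 CPM in ST2-negative cells and lay at the floor in ST2-positive cells. The edgeR adjusted p of these genes was at most 2.25e-06.

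**Figure D3:**
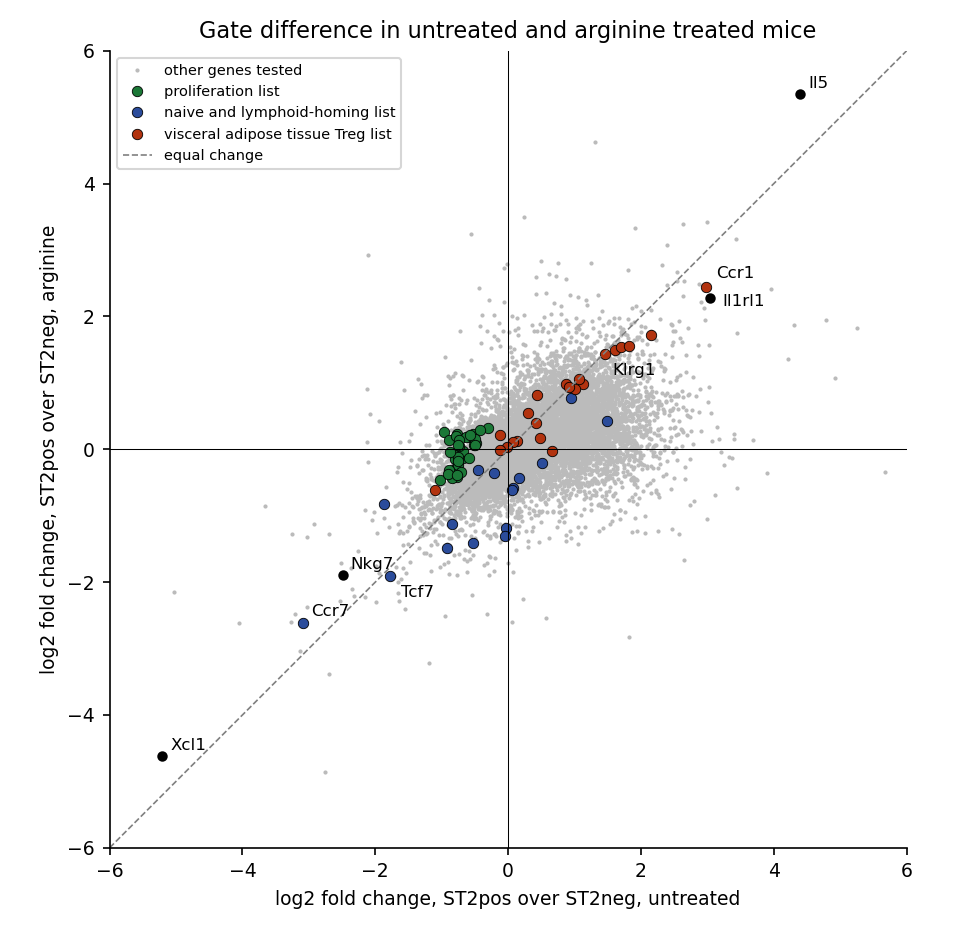
Log2 fold change of ST2-positive over ST2-negative cells in arginine-treated mice (vertical axis) against that in untreated mice (horizontal axis). Each point is a gene. Colours mark members of the proliferation, naive and lymphoid-homing, and visceral adipose tissue Treg lists, whether or not they passed the test. The plot holds 15470 genes, leaves 6 outside its axes at a limit of 6, and shows Il1rl1 and Il5 high and Ccr7 low in both treatments.

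In the list of visceral adipose tissue Treg genes, 14 of 22 tested genes were higher in ST2-positive cells of untreated mice, among them Dgat2, an enzyme of triglyceride synthesis, and Ccr2, a chemokine receptor. Lower was 1, the decoy receptor gene Il1r2. Adjusted over the list alone, 15 were higher and 1 lower, and camera gave an adjusted p of 5.47e-14 (adjusted p = 0.0486 with an estimated correlation). Of 10 Th2-associated genes 6 were higher and none lower (7 adjusted over the list alone), among them Ccr4 and Il17rb (adjusted p = 8.85e-07, and 0.0486 with an estimated correlation). Of 13 Th1-associated genes 6 were lower, among them Tbx21, the Th1 transcription factor, Cxcr3 and Ccl5, and 5 were higher. Adjusted over the list alone 7 were lower and 5 higher, with an adjusted p of 0.0287 that became 0.402 with an estimated correlation. Of 16 naive and lymphoid-homing genes 4 were lower, among them Tcf7 and S1pr1, and 3 were higher, among them Il7r. The numbers were the same adjusted over the list alone, and the list did not pass with camera (adjusted p = 0.136). It passed as lower with fry (0.035) and with the no-feature share as a covariate, an alternative chosen after the data had been seen (0.00125). In the suppressive effector list 8 of 17 genes were higher, among them Gzmb and Fgl2, and 3 were lower, among them Tigit (8 and 4 adjusted over the list alone). The adjusted p of 0.0287 became 0.426 with an estimated correlation. In the Treg identity list 5 of 18 were higher, among them Il10ra, and 4 lower, among them Izumo1r and Lrrc32 (5 and 6 adjusted over the list alone, adjusted p = 0.711).

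Cell division genes were lower in ST2-positive than in ST2-negative cells of untreated mice. Of 34 proliferation genes 32 were lower, and all 34 when adjusted over the list alone, with a median of -0.75. Camera gave an adjusted p of 1.96e-25 (adjusted p = 0.23 with an estimated correlation). Mcm5 and Mcm6, subunits of the replicative helicase, were at -1.02 and -0.85 (SE 0.104 and 0.103), and the ribonucleotide reductase gene Rrm2 at -0.91 (SE 0.12). With the covariate 8 of the 34 passed and the median was -0.49. Ribosomal protein genes moved the same way, with 67 of 79 lower (74 adjusted over the list alone, median -0.37, adjusted p = 1.32e-25, and 0.372 with an estimated correlation), for example Rpl8 at -0.54. Of the 79, 4 were lower with the covariate, where the median was -0.314 (camera adjusted p = 4.05e-22). Oxidative phosphorylation genes moved this way too, with 42 of 76 lower (54 adjusted over the list alone, adjusted p = 1.03e-16, and 0.372 with an estimated correlation). Of the 76, 0 passed with the covariate, where the median was -0.157 (camera adjusted p = 4.6e-06). Lower too were the mitochondrial rRNAs mt-Rnr1 and mt-Rnr2, both of the 2 tested (adjusted p = 0.0302, and 0.372 with an estimated correlation). The call for mt-Rnr1 was lost without ST2-negative untreated replicate 2 or ST2-positive untreated replicate 1 (adjusted p = 0.051 and 0.059). In glycolysis and hypoxia 11 of 28 were lower, among them Tpi1, and 2 higher, among them Egln3, with 13 and 3 adjusted over the list alone (adjusted p = 6.21e-05, 0.402 with an estimated correlation and 0.264 with the covariate). The no-feature share, 33.3% in the ST2-negative and 47.3% in the ST2-positive libraries, separated the same libraries as these 5 groups.

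Genes of the T cell receptor apparatus were lower in 10 of 20 cases in ST2-positive cells of untreated mice, among them the receptor constant genes Trbc1 and Trbc2 (11 adjusted over the list alone, adjusted p = 3.32e-05, and 0.372 with an estimated correlation). Of the 20, 2 were lower and 1 higher with the covariate, where the median was -0.0741 (camera adjusted p = 0.0416). Of 26 NF-kB targets 10 were higher, among them Nfkbiz, Birc3 and Icam1 (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.000181, and 0.372 with an estimated correlation). Immediate-early and heat-shock genes went both ways, with 12 of 31 higher, among them Nr4a1, Zfp36 and Atf3, and 5 lower (17 and 8 adjusted over the list alone, adjusted p = 0.0279, and 0.426 with an estimated correlation). Chemokine receptor and adhesion genes were higher in 10 and lower in 6 of 22 cases, as when adjusted over the list alone (adjusted p = 0.0147, and 0.372 with an estimated correlation). Of 23 ATF4 targets of the amino acid response 5 were lower and 1 higher (7 and 1 adjusted over the list alone). The adjusted p was 0.0287, and became 0.426 with an estimated correlation and 0.593 with the covariate.

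The lists of arginine, fatty acid, cholesterol, unfolded protein, interferon, sensing and Th17 genes did not pass with camera between the gates of untreated mice, and 3 of them passed with the covariate. With fry the arginine list passed as lower (adjusted p = 0.0477) and the sensing list as higher (0.00607). Of 29 arginine and polyamine genes 5 were lower and 1 higher, as adjusted over the list alone. Of these, Slc7a2, Azin1, Ass1 and Srm lost their call with the covariate (adjusted p = 0.727, 0.246, 0.461 and 0.639). So did Azin1, Ass1 and Srm without ST2-positive untreated replicate 2 (0.0709, 0.066 and 0.128), and Srm without ST2-negative untreated replicate 1 (0.0553). This list's median was -0.14 and its mean 0.03, and the test, which gave the sign of the median, did not pass (adjusted p = 0.269). In the fatty acid list 4 of 41 genes were higher, among them Dgat1, and 2 lower, among them Scd2, as adjusted over the list alone. Its median was -0.03 and its mean 0.12, and the test gave the mean's sign (adjusted p = 0.711). The cholesterol list had 3 higher, among them Cyp51, and 1 lower of 24 (adjusted p = 0.289). The unfolded protein list had 2 higher, among them Ern1, and 1 lower of 21 (adjusted p = 0.226). The interferon list had 6 higher, among them the GTPase genes Igtp and Gbp2, and 2 lower of 35 (adjusted p = 0.187). The numbers of these 3 lists were the same when adjusted over the list alone. With the covariate these 3 passed as higher, with the preset correlation (adjusted p = 0.0037, 6.53e-06 and 8.47e-08). Of 17 microbial and dietary sensing genes 2 were higher, the receptor gene Gpr15 and Tiparp (adjusted p = 0.0845), and of 8 Th17-associated genes Ccr6 was lower (adjusted p = 0.924), again as adjusted over the list alone. Tiparp and Ccr6 lost their call with the covariate (adjusted p = 0.195 and 0.606), and Ccr6 also without ST2-negative untreated replicate 1 or ST2-positive untreated replicate 2 (0.05 and 0.0634).

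Markers of other cells also differed between the gates of untreated mice. Of 25 macrophage and dendritic cell genes 9 were higher in ST2-positive cells, among them Itgam, H2-Eb1, H2-Ab1 and Cd74 (10 adjusted over the list alone, median 0.49, adjusted p = 9.2e-05, and 0.402 with an estimated correlation). The number was 5 without ST2-negative untreated replicate 3 or ST2-positive untreated replicate 2, and the median 0.27 without the latter. Of 16 B cell genes 5 were higher, as adjusted over the list alone, among them Ighm, at 1117 ± 130 and 2242 ± 357 CPM, and Igkc (adjusted p = 0.0024, 0.372 with an estimated correlation and 0.214 with the covariate). Of 7 neutrophil and mast cell genes 3 were higher, among them Mmp9 (5 adjusted over the list alone, adjusted p = 0.00535, and 0.221 with an estimated correlation). In the list of CD8 T, NK and innate lymphoid cells 2 of 8 were higher, Calca and Gzmb, and 2 lower, among them Xcl1, as adjusted over the list alone. The median was 0.10 and the mean -0.33, and camera gave the median's sign and did not pass, while fry passed as higher (adjusted p = 0.284 and 8.63e-05). The mesothelium and stroma list had a median of 0.88 with 1 of 18 genes higher, Vwf (camera adjusted p for the list = 0.0845). The call for Vwf was lost with the covariate (adjusted p = 0.794) and without ST2-negative untreated replicates 1 or 2 or ST2-positive untreated replicate 2 (0.0528, 0.0899 and 0.137). The thymocyte list had a median of 0.46 over 5 genes (camera adjusted p = 0.375) and the erythroid and platelet list one of 0.31 over 2 (camera adjusted p = 0.817), with no gene past the threshold.

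In all, 3246 of 15476 genes differed between the gates in untreated mice, 1532 higher and 1714 lower in ST2-positive cells. Of the 990 genes at least 2-fold higher, 734 averaged under 10 CPM, and of the 166 at least 2-fold lower, 54 did. The count was 1594 without ST2-positive untreated replicate 2, the library with the highest no-feature share (52.5%), and 662 with that share as a covariate, of which 586 were shared, while 115 of the 3246 changed sign. The number higher was 904, 913, 729 and 1001 without ST2-negative untreated replicates 1 or 3 or ST2-positive untreated replicates 2 or 3, and the number lower 865 without ST2-positive untreated replicate 2.

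The same comparison in arginine-treated mice asked whether the gates still differ under treatment. ST2-positive cells were again higher in Klrg1, from 462 ± 4.37 to 1359 ± 48.3 CPM, in Gata3, from 687 ± 31.6 to 1289 ± 50.9 CPM, and in Areg, from 478 ± 48.6 to 942 ± 117 CPM. Il5 was at 31.9 ± 8.2 CPM in ST2-positive cells and near the floor in ST2-negative cells. Odc1, the entry enzyme of polyamine synthesis, was higher, from 2093 ± 156 to 3054 ± 177 CPM (log2 0.55, SE 0.0757, adjusted p = 2.21e-05). Pcsk1, a protease that activates peptide hormones, was 2.47 higher (SE 0.199), and the leukotriene receptor gene Ltb4r1 was higher too (adjusted p = 2.31e-10). Calca, Nmur1 and Ccr1 were higher by 2.54, 2.49 and 2.45 (log2), and the suppressive cytokine gene Il10 by 0.81 (SE 0.119). Ccr7 was at -2.61 (SE 0.149), Cxcr5 at -2.62 (SE 0.419), the naive T cell factor Tcf7 at -1.91 (SE 0.184), the Rab regulator Tbc1d4 at -2.31 (SE 0.183) and Nkg7 at -1.89 (SE 0.148).

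Naive and lymphoid-homing genes were lower in ST2-positive cells of arginine-treated mice, 9 of 16, among them S1pr1 at -1.48 (SE 0.152), Tcf7 and Ccr7, while Il7r was higher. Adjusted over the list alone 10 were lower and 1 higher, and camera passed with the preset and with an estimated correlation (adjusted p = 2.53e-10 and 0.0269). In the visceral adipose tissue Treg list 14 of 22 were higher and 1 lower (15 and 1 adjusted over the list alone, adjusted p = 2.07e-24, and 0.00696 with an estimated correlation), and in the Th2 list 6 of 10 were higher (7 adjusted over the list alone, adjusted p = 4.25e-10, and 0.00696 with an estimated correlation). NF-kB targets were higher in 11 and lower in 1 of 26 cases, among the higher Nfkbiz and Birc3 (15 and 2 adjusted over the list alone, adjusted p = 6.27e-11, and 0.136 with an estimated correlation). Suppressive effector genes were higher in 5 cases, among them Gzmb, Il10 and Fgl2, and lower in 3, among them Lag3 (9 and 3 adjusted over the list alone, adjusted p = 0.000351, and 0.278 with an estimated correlation). Proliferation genes were lower in 3 of 34 cases (6 adjusted over the list alone), and the list, with a median of 0.03, a mean of -0.03 and a test of the mean's sign, did not pass (adjusted p = 0.317), although it did without ST2-positive arginine replicate 3 (adjusted p = 0.0278). By edgeR 2 were higher and 0 lower without ST2-negative arginine replicate 2, and 0 were higher and 1 lower without ST2-positive arginine replicate 1. Ribosomal protein genes were lower in 15 of 79 cases (41 adjusted over the list alone, adjusted p = 7.32e-18, and 0.303 with an estimated correlation). Of the macrophage and dendritic cell markers 7 of 25 were higher, as adjusted over the list alone, among them H2-Eb1, H2-Ab1, H2-Aa and Cd74 (adjusted p = 1.42e-07, and 0.278 with an estimated correlation). Of 16 B cell genes Ighm was higher (2 adjusted over the list alone, adjusted p = 0.00075, and 0.28 with an estimated correlation). The call for Ighm was lost with DESeq2 (adjusted p = 0.106) and without ST2-negative arginine replicates 2 or 3 or ST2-positive arginine replicate 2 (0.0623, 0.0965 and 0.277). Of 7 neutrophil and mast cell genes Mmp9 was higher, as adjusted over the list alone (adjusted p = 0.00268, and 0.136 with an estimated correlation). Oxidative phosphorylation genes were lower in 8 of 76 cases (20 adjusted over the list alone, adjusted p = 1.63e-11, and 0.334 with an estimated correlation), and in 2 with the covariate.

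A total of 970 genes differed between the gates in arginine-treated mice, 478 higher and 492 lower in ST2-positive cells, and the count was 638 without ST2-positive arginine replicate 1. The number lower was 302, 242 and 296 without ST2-negative arginine replicates 1, 2 and 3, and 249 and 300 without ST2-positive arginine replicates 1 and 3. Of the genes past the threshold, 385 were higher and 353 lower under both treatments, against 47.3 and 54.5 expected by chance, and 1 went opposite ways. Of the 3246 genes that differed in untreated mice, 90.88% had the same sign in arginine-treated mice. Their median difference in that direction was 0.33 there, against 0.69 in untreated mice. The genes were picked by the untreated comparison, which raises the 0.69, so these medians do not measure a change of the gate difference with arginine.

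In ST2-negative Tregs the comparison of arginine-treated with untreated mice asked what the treatment changed in these cells. The deposited files number the libraries of the 2 treatments in separate series, and whether these are batches is not given in the sources used here. Il10 (chromosome 1 at 131019845 to 131024974) fell from 244 ± 35.1 to 109 ± 10.3 CPM, and Gzmb, the granule protease granzyme B (chromosome 14 at 56258838 to 56262260), from 422 ± 70.7 to 230 ± 15 CPM. The heat-shock gene Hspa1b fell from 276 ± 62.5 to 119 ± 16.3 CPM and Hsp90aa1 from 608 ± 16.3 to 413 ± 10.2 CPM, and Jun, a subunit of the AP-1 factor, from 229 ± 12.5 to 156 ± 15.8 CPM. Some genes with more RNA in ST2-positive cells rose, while Il10 and Gzmb, also among these, fell. Il1rl1 was 1.04 higher (SE 0.092, adjusted p = 6.46e-07), Dgat2 0.81, Ccr3 1.07, Ccr2 0.60, Mmp9 0.90 and Calca 1.11 higher.

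Bach2 and Satb1, transcription factors of resting T cells, rose with arginine in ST2-negative cells, from 28.6 ± 5.49 to 65.9 ± 13.9 CPM and from 73.6 ± 4.72 to 121 ± 14.9 CPM, and the sialyltransferase gene St8sia6 was 1.51 higher (SE 0.229). Retnla, a product of alternatively activated macrophages, was at -2.01 (SE 0.365), the chemokine gene Ccl9 at -1.41 (SE 0.226), the inflammatory cytokine gene Il1b at -1.25 (SE 0.207), the histone gene H2bc4 at -1.25 (SE 0.225) and the kinase gene Stk32c at -1.52 (SE 0.287). Nkg7 was at -0.79 (SE 0.137), Lgals1, which encodes galectin-1, at -0.49 (SE 0.0968), Phgdh, the entry enzyme of serine synthesis, at -0.54 (SE 0.11) and the glycolytic gene Gpi1 at -0.44 (SE 0.0917). Their edgeR adjusted p was at most 0.0127. Arg1, which encodes an enzyme that breaks down arginine (chromosome 10 at 24915221 to 24927484), fell from 25.3 ± 7.22 to 8.97 ± 6.48 CPM (adjusted p = 0.0204). Its call was lost without ST2-negative arginine replicates 1 or 3 or untreated replicates 1 or 3 (adjusted p = 0.103, 0.107, 0.0626 and 0.108) and with the no-feature share as a covariate (adjusted p = 0.0812). Odc1 and the arginine transporter gene Slc7a1 did not pass (adjusted p = 0.955 and 0.155), and neither did Pparg, Gata3, Klrg1 or Areg.

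**Figure D4:**
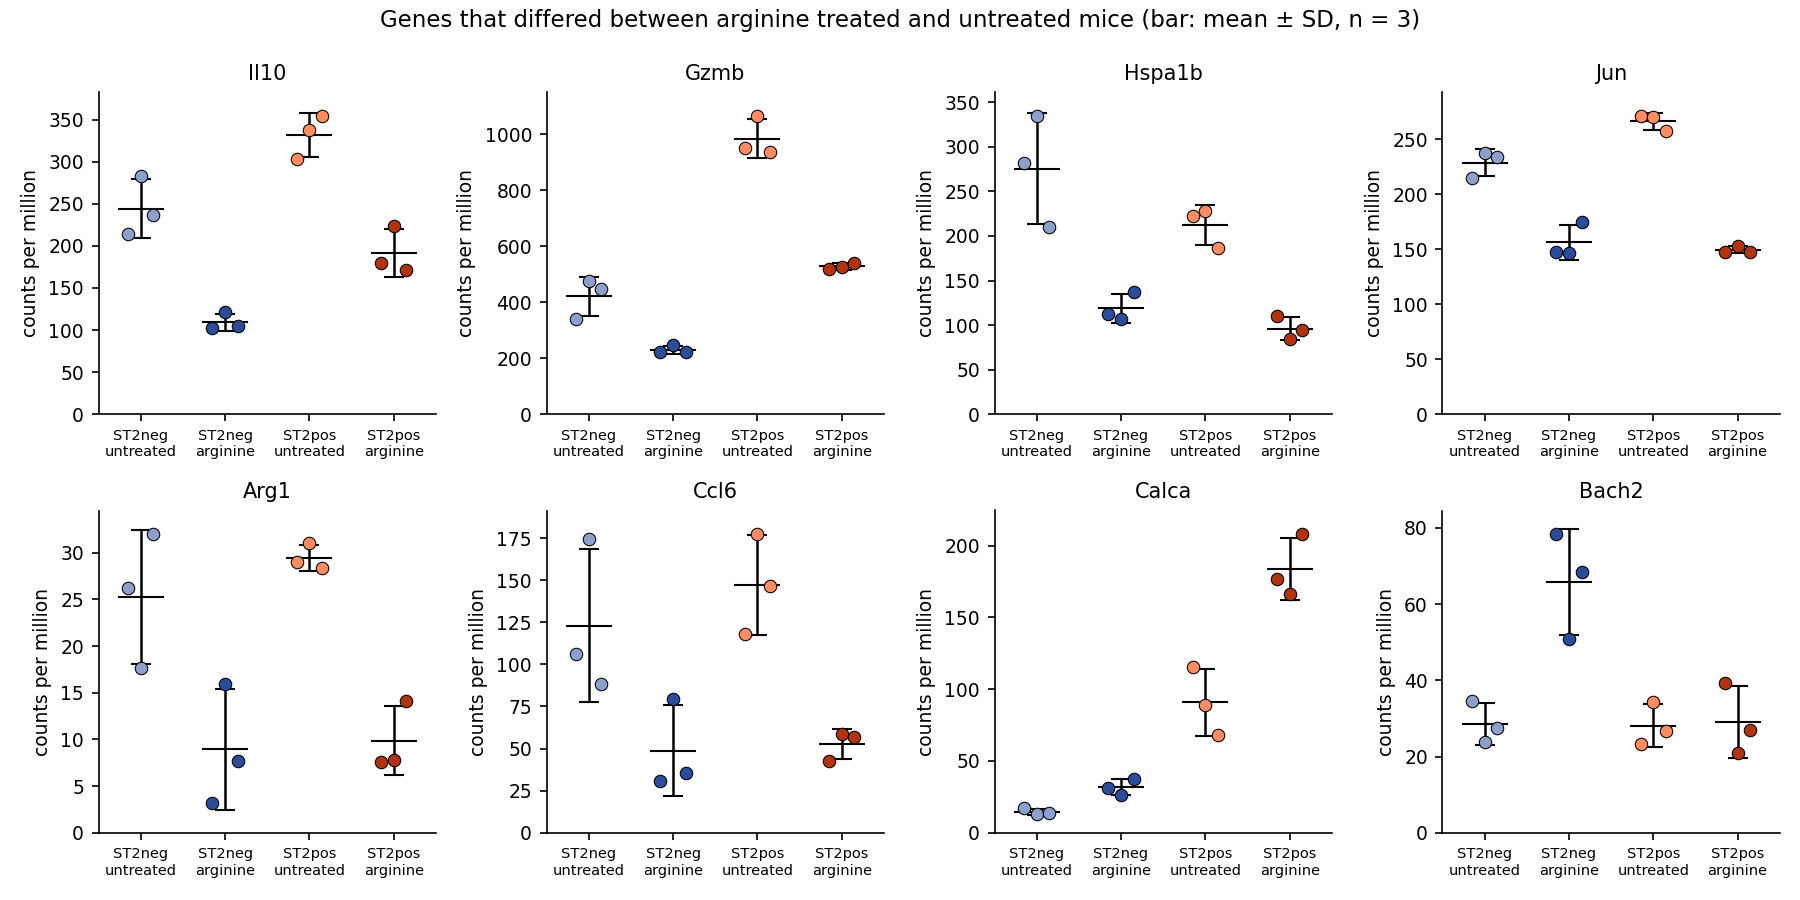
Expression in CPM (vertical axis) of 8 named genes by group (horizontal axis); points are libraries, and bars show mean ± SD (n = 3). Il10, Gzmb, Hspa1b, Jun, Arg1 and Ccl6 have lower and Calca higher means with arginine in both gates, while Bach2 has a higher mean in ST2-negative cells.

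Proliferation genes were lower with arginine in ST2-negative cells, 12 of 34, among them Ube2c and Mcm3 (31 adjusted over the list alone, median -0.41, adjusted p = 3.51e-25, and 0.274 with an estimated correlation). The calls for Ube2c and Mcm3 were lost with the no-feature share as a covariate (adjusted p = 0.0724 and 0.0727) and without ST2-negative arginine replicate 3 (0.0576 and 0.0628). That for Ube2c was lost also without untreated replicate 2 (0.0655) and that for Mcm3 without arginine replicate 1 (0.0695). By edgeR the number of the 34 that passed was 0 with the covariate and without arginine replicates 1 or 3 or untreated replicate 2, 3 without untreated replicates 1 or 3, and 22 without arginine replicate 2. The list's median with the covariate was -0.282 (camera adjusted p = 4.37e-16 with the preset correlation). Naive and lymphoid-homing genes were higher in 4 of 16 cases, among them Satb1 and Bach2 (7 higher and 1 lower adjusted over the list alone, adjusted p = 2.08e-07, and 0.269 with an estimated correlation). Without arginine replicate 1 there were 2, and the list's median was 0.24 against 0.41. Immediate-early and heat-shock genes were lower in 8 of 31 cases and higher in 2 (15 and 3 adjusted over the list alone, median -0.29, adjusted p = 2.85e-08, and 0.274 with an estimated correlation). Suppressive effector genes were lower in 4 of 17 cases, among them Il10, Gzmb and Lgals1 (6 lower and 3 higher adjusted over the list alone), with an adjusted p of 0.00483 that became 0.332 with an estimated correlation and 0.104 with the covariate. Glycolysis and hypoxia genes were lower in 5 of 28 cases (10 adjusted over the list alone, adjusted p = 2.85e-08, and 0.274 with an estimated correlation), and chemokine receptor genes higher in 6 of 22 (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.00483, and 0.274 with an estimated correlation). In arginine and polyamine metabolism Arg1 alone of 29 genes passed, as adjusted over the list alone, and the list did not (adjusted p = 0.103).

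Markers of macrophages and dendritic cells were lower with arginine in the ST2-negative libraries, 5 of 25 (10 adjusted over the list alone, median -0.65, adjusted p = 5.07e-08, and 0.274 with an estimated correlation), beside the falls of Retnla, Ccl9, Il1b and Arg1. C1qb, a complement gene of macrophages, was among them, at 66.7 ± 25.2 and 31.1 ± 8.12 CPM without and with arginine. Its call was lost with the covariate (adjusted p = 0.0778), with DESeq2 (0.0713) and without ST2-negative arginine replicates 1 or 3 or untreated replicates 1 or 2 (0.158, 0.136, 0.143 and 0.104). By edgeR the number of the 25 that passed was 0 without any of these 4 libraries and with the covariate, and 9 without arginine replicate 2. B cell markers went the other way, with Ighm and Igkc of 16 tested higher (3 adjusted over the list alone, adjusted p = 2.54e-05, and 0.274 with an estimated correlation), Ighm from 1117 ± 130 to 1903 ± 153 CPM. Ribosomal protein genes were lower in 2 of 79 cases (6 adjusted over the list alone, median -0.22, adjusted p = 4.44e-23, and 0.274 with an estimated correlation), and mt-Rnr2 fell by 0.46 (log2).

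With arginine 324 genes changed in ST2-negative cells, 182 higher and 142 lower. The count depends on single libraries: it was 712 without ST2-negative arginine replicate 2, whose no-feature share was 30.6%, 93 and 95 without arginine replicates 1 and 3, and 166, 94 and 113 without untreated replicates 1, 2 and 3. With the no-feature share as a covariate it was 185, of which 134 were shared, and with DESeq2, limma voom and no filter it was 509, 767 and 535, of which 307, 313 and 284 were shared.

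The same treatment was compared in ST2-positive Tregs. Il10 fell from 332 ± 26 to 191 ± 28.2 CPM, Gzmb from 985 ± 70.8 to 529 ± 12.4 CPM, Jun from 266 ± 7.44 to 149 ± 3.21 CPM and Hspa1b from 212 ± 22.7 to 96.1 ± 12.9 CPM. Klf2, a transcription factor that controls T cell exit from lymphoid organs, fell from 177 ± 6.22 to 92.9 ± 10.5 CPM, and the chemokine gene Cxcl2 from 162 ± 26.4 to 85.8 ± 14.2 CPM. Calca rose from 90.7 ± 23.6 to 184 ± 21.5 CPM, Mmp9, a matrix protease, from 72.5 ± 10.3 to 133 ± 12.8 CPM, Ier5l from 25.6 ± 6.05 to 69.9 ± 5.23 CPM and the membrane protein gene Ms4a4b from 218 ± 28.6 to 364 ± 19.2 CPM. Nt5e, which encodes the adenosine-producing enzyme CD73, was 0.55 higher (SE 0.09), and H2bc4 and Ccl9 were at -1.42 and -1.28 (SE 0.228 and 0.216). The edgeR adjusted p of these genes was at most 0.00365. Hspa1a, whose sequence is nearly identical to that of Hspa1b, was lower in both gates as well. Reads of these genes cannot be assigned to either with certainty.

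Of the genes of arginine use, Odc1 and Arg1 passed in ST2-positive cells, and both calls depended on single libraries. Odc1 rose from 2355 ± 156 to 3054 ± 177 CPM (log2 0.38, SE 0.0756, adjusted p = 0.0154), and the call was lost without ST2-positive arginine replicates 2 or 3 or untreated replicates 2 or 3 (adjusted p = 0.156, 0.0854, 0.0969 and 0.175). Odc1 was not among the genes that passed the interaction test, so its arginine effect was not shown to differ between the gates. Arg1 fell from 29.5 ± 1.39 to 9.84 ± 3.7 CPM (adjusted p = 0.0236), and its call was lost without arginine replicates 1 or 2 or untreated replicates 1, 2 or 3 (adjusted p = 0.162, 0.15, 0.0601, 0.152 and 0.0768). Ccl6, a chemokine of myeloid cells, fell from 147 ± 29.5 to 52.7 ± 8.82 CPM, a call lost without untreated replicate 2 (adjusted p = 0.0588). The pancreatic elastase genes Cela2a and Cela1 also passed as lower, but their level came from ST2-positive untreated replicate 2 (adjusted p = 0.333 and 0.452 without it), and the calls also ended without arginine replicate 1 (0.0551 and 0.106) and, for Cela1, without arginine replicates 2 or 3 (0.0921 and 0.1). Il1rl1 did not pass (log2 0.28, SE 0.0867, adjusted p = 0.191), nor did Slc7a1 (adjusted p = 0.78).

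Immediate-early and heat-shock genes were lower with arginine in ST2-positive cells in 5 of 31 cases and higher in 1 (17 and 2 adjusted over the list alone, median -0.25, adjusted p = 1.43e-08, and 0.389 with an estimated correlation). Suppressive effector genes were lower in 3 of 17 cases, among them Gzmb and Il10 (6 lower and 1 higher adjusted over the list alone), with a median of 0.01, a mean of -0.25 and a test of the mean's sign (adjusted p = 0.0173, and 0.557 with an estimated correlation). The proliferation list had a median of 0.24, and 9 of its 34 genes were higher adjusted over the list alone, though its members did not pass over all genes (camera adjusted p = 9.24e-13, and 0.557 with an estimated correlation). Its median was 0.12 without untreated replicate 2 and 0.16 without arginine replicate 3. Chemokine receptor genes were higher in 1 of 22 cases, Ccr2 (8 higher and 3 lower adjusted over the list alone, adjusted p = 2.6e-05, and 0.389 with an estimated correlation), and interferon genes in 1 of 35, Ifi44 (3 adjusted over the list alone, adjusted p = 3.08e-05, and 0.557 with an estimated correlation). The call for Ccr2 was lost without arginine replicates 1 or 2 or untreated replicates 2 or 3 (adjusted p = 0.0888, 0.107, 0.0942 and 0.197), and that for Ifi44 with limma voom (0.0571) and without arginine replicates 1 or 3 or untreated replicates 2 or 3 (0.256, 0.0947, 0.277 and 0.172). In arginine and polyamine metabolism Odc1 was higher and Arg1 lower of 29 tested, as adjusted over the list alone (adjusted p = 0.197). Macrophage and dendritic cell markers had a median of -0.37, and 9 of 25 were lower adjusted over the list alone (camera adjusted p = 5.99e-08, and 0.557 with an estimated correlation), beside the falls of Arg1, Ccl6, Ccl9 and Cxcl2. Their median was -0.60 without arginine replicate 2 and -0.55 without untreated replicate 3. B cell markers had a median of 0.28 (camera adjusted p = 0.000894, and 0.557 with an estimated correlation) and ribosomal protein genes one of -0.09 (camera adjusted p = 3.08e-05, and 0.633 with an estimated correlation).

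In ST2-positive cells 98 genes changed with arginine, 53 higher and 45 lower. The count was 25 without untreated replicate 2, 55 without untreated replicate 3, 40 and 54 without arginine replicates 1 and 2, 168 with the no-feature share as a covariate, 196 with DESeq2 and 269 without a filter. The number higher was 81 without untreated replicate 1, and the number lower 28 without arginine replicate 3. Between the gates, which share no libraries, 30 genes were higher and 24 lower with arginine in both, and 1 went opposite ways. By chance 0.623 and 0.413 are expected if the gates are independent. The labels do not say whether both gates come from the same mice. A batch that follows the treatment would give such an overlap too. Of the 324 genes that changed in ST2-negative cells, 78.4% had the same sign in ST2-positive cells.

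The interaction asked which genes responded to arginine differently in the gates. Of the 6 genes that passed, 5 had a higher value in ST2-positive cells, among them the cell cycle genes Bub1, Rrm1 and Top2a. Bub1, a kinase of the spindle checkpoint, was at 66.3 ± 6.23 and 43.6 ± 4.81 CPM in ST2-negative cells without and with arginine and at 34.1 ± 6.53 and 52 ± 7.53 CPM in ST2-positive cells. Top2a, the DNA topoisomerase of dividing cells (chromosome 11 at 98992943 to 99024189), was at 365 ± 3.67 and 278 ± 35.3 CPM in ST2-negative cells and at 244 ± 25.8 and 322 ± 38.5 CPM in ST2-positive cells. Il1rl1 went the other way, with the larger arginine effect on the log2 scale in ST2-negative cells. In CPM the rise of its mean was larger in ST2-positive cells. The gates were sorted on the product of this gene, so its term is no independent finding between them. The interaction terms were 1.22 for Bub1 (SE 0.214), 1.02 for Dtl, a factor of the replication checkpoint (SE 0.178), 1.01 for Wdr90 (SE 0.176), 0.83 for Rrm1, a subunit of ribonucleotide reductase (SE 0.153), 0.79 for Top2a (SE 0.148) and -0.77 for Il1rl1 (SE 0.126), with edgeR adjusted p from 0.0292 to 0.0453.

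Of the 34 proliferation genes 3 passed the interaction test over all genes and 33 adjusted over the list alone (median 0.65, adjusted p = 2.35e-47, and 0.179 with an estimated correlation). The 3 rest on single libraries: by edgeR 12 passed without ST2-negative arginine replicate 2, 10 without ST2-positive arginine replicate 1, 1 without ST2-negative untreated replicate 1, and 2 without ST2-positive untreated replicates 1 or 3. It was 0 without any 1 of the other 7 libraries and with the covariate. The list's median with the covariate was 0.478 (camera adjusted p = 6.26e-32 with the preset correlation). The mean log2 CPM of the list was 7.27 ± 0.0363 and 6.84 ± 0.152 in ST2-negative cells without and with arginine and 6.56 ± 0.202 and 6.80 ± 0.209 in ST2-positive cells (SD, n = 3). An exact permutation test of this difference of 0.67 over 400 relabellings gave a two-sided p of 0.015, or 0.12 adjusted over the 8 list scores tested. Such relabellings move treatment labels within each gate. Their p therefore tests for no arginine effect in either gate, not for an equal effect in both. The naive and lymphoid-homing list had a median of -0.58 and 5 of 16 genes lower adjusted over the list alone (adjusted p = 6.5e-06, and 0.179 with an estimated correlation), and its score differed by -0.51 (exact permutation p = 0.065, adjusted 0.26). With the covariate its median was -0.29 (camera adjusted p = 0.00289).

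**Figure D5:**
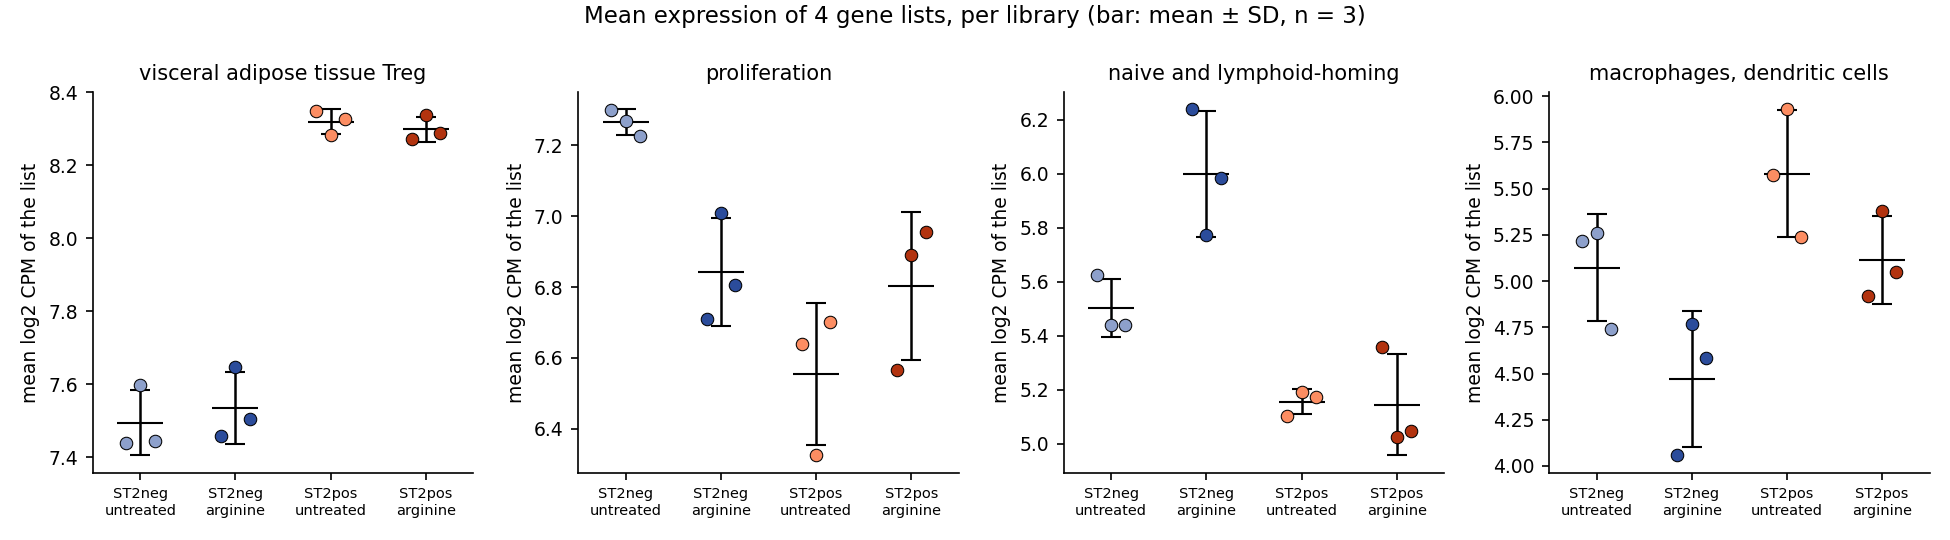
Mean log2 CPM of the genes of 4 lists (vertical axis) by group (horizontal axis); points are libraries, and bars show mean ± SD (n = 3). Mean proliferation scores are 7.27 without and 6.84 with arginine in ST2-negative cells, and 6.56 and 6.80 in ST2-positive cells.

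By the interaction test 6 genes passed, 5 with a higher and 1 with a lower value in ST2-positive cells, and 1260 had an unadjusted p under 0.05, against 774 expected by chance. The number was 49 with DESeq2, 46 with limma voom and 122 without a filter, and each of these sets included the same 6 genes. It was 0 with edgeR with the no-feature share as a covariate, where 932 had an unadjusted p under 0.05. It was 62 and 25 without ST2-negative arginine replicate 2 and ST2-positive arginine replicate 1, 3 without ST2-positive untreated replicate 3, and 0 without any of ST2-negative arginine replicates 1 or 3, ST2-negative untreated replicate 2, ST2-positive arginine replicates 2 or 3, or ST2-positive untreated replicate 2. In these 6 edgeR fits 912 to 1441 genes had an unadjusted p under 0.05.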

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

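The tests of reads in no annotated feature, of ST2-positive cells in the ST2-negative sort and of macrophage RNA were chosen only after the results were seen. Those of the splits of the libraries and of the sort day were not.

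The arginine effect differed between ST2-positive and ST2-negative cells in 6 genes by the interaction test of edgeR. The difference (log2) was 1.22 for Bub1, 1.02 for Dtl, 1.01 for Wdr90, 0.83 for Rrm1, 0.79 for Top2a and -0.765 for Il1rl1, and none of the 6 passed with the no-feature share as a covariate. Of 100 splits drawn from the relabellings of the 12 libraries, the real one included, 9 gave at least 6 genes. These splits move treatment labels within each gate, so they can carry a difference between the treatments that both gates share into the interaction. The 9 in 100 thus does not measure chance for an interaction, and chance cannot be excluded for this count. The highest other split gave 577 genes, and it exchanged the treatment labels within 1 gate. A count this far above the real one points to a structure of the samples, a difference between the treatments that both gates share. Whether arginine or a batch that follows the treatment made it cannot be told.

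Of the gene lists, 7 differed between the gates in their arginine effect by camera with the preset correlation, and none with an estimated correlation. The median difference was 0.647 for proliferation (adjusted p = 2.35e-47, and 0.179 estimated), -0.582 for naive and lymphoid-homing genes (6.5e-06, and 0.179 estimated) and 0.223 for Th1-associated genes (0.0121, and 0.846 estimated). It was 0.186 for glycolysis and hypoxia, 0.0996 for oxidative phosphorylation, 0.0882 for the T cell receptor apparatus and 0.132 for ribosomal proteins (adjusted p = 0.000285, 0.000136, 0.0458 and 6.71e-08, each 0.863 estimated). With the no-feature share as a covariate the Th1, glycolysis, oxidative phosphorylation and T cell receptor lists did not pass (adjusted p = 0.236, 0.639, 0.835 and 0.796), and the last turned its direction.

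For the comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and 1 split of each 10, the real one, gave a count as large. The real counts were 3246 and 970 between the gates of untreated and of arginine-treated mice, where the highest other splits gave 1 and 2. They were 324 and 98 with arginine in ST2-negative and ST2-positive cells, where the highest other splits gave 1 and 1. Each other split mixes libraries of both real groups on both sides. A real difference then adds to the spread within the sides and lowers the count, so these low counts do not measure what chance gives.

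The share of reads in no annotated feature, a measure that no comparison of genes used, was 47.3% in ST2-positive libraries of untreated mice, above all 3 ST2-negative ones (mean 33.3%). Reads in no annotated feature are therefore a candidate cause of the gate difference. Whether they lie within genes, between genes or on the other strand cannot be told from the counts. The median of the visceral adipose tissue Treg list, which was fixed beforehand, did not shrink. It was 0.764 without and 0.878 with the no-feature share as a covariate, with 15 of 22 genes past the threshold either way. This argues against these reads as the cause for that list but cannot exclude them. The share did not overlap between the gates of untreated mice, so the covariate's slope rests on the spread within groups. That spread was largest in ST2-negative cells of arginine-treated mice (SD 8.35), where replicate 2 lay apart from the others. The argument for the list is therefore weak, since the slope rests largely on a library outside the comparison. For the 734 genes at least 2-fold higher and under 10 CPM, the median went from 1.71 to 0.795. These reads may account for a part of their difference. The median of the single genes' SEs went from 0.505 to 0.666, and 16 still passed, since the fold shrank and the error grew. These genes and the 256 that follow were picked by fold and p in the fit without the covariate. Such a choice alone can shrink the median in another fit, so the fall does not decide the cause. For the 256 such genes of 10 CPM or more (1.34 to 1.01) and for the proliferation list (-0.745 to -0.489), 75.4% and 65.7% of the median was kept, between the bounds set for either reading, so that these reads and a difference between the cells, which the design names, cannot be told apart.

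Il1rl1, the gene of the sort marker, was at 338 CPM in ST2-negative cells with arginine and at 164 CPM without, and ST2-positive cells in the ST2-negative sort are a candidate cause. Il1rl1 alone would need 11.8% of ST2-positive RNA. The 96 other genes used passed under both treatments and were at least 2-fold higher in ST2-positive cells. They averaged at least 10 CPM over all libraries. Group means that picked these genes also enter their shares, so the choice can shift the shares. Their median was 6.6% (95% bootstrap interval 2.93 to 8.16, quartiles -3.12 to 12.7), with 62 of the 96 above 0. That median lies below what Il1rl1 needs, but the upper quartile of the genes, 12.7%, lies above it, and 28 of the 96 reached it, so this cause and a rise within the cells cannot be told apart. Sorting on different days with a different ST2 gate is open too, since 0 columns of the labels give a sort day and the deposited files number the 2 treatments in separate series. A response of ST2-negative cells to arginine, the reading the design names, was not tested apart from these.

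Arg1, Ccl6, Ccl9 and Retnla, genes with high expression in some macrophages, were at -1.33 to -2.01 (log2) with arginine in ST2-negative and at -1.2 to -1.59 in ST2-positive cells, where Retnla did not pass, and the call for Ccl6 in ST2-negative cells was lost without arginine replicates 1 or 3 or untreated replicate 2 (adjusted p = 0.0505, 0.0567 and 0.0595). RNA of macrophages in the sorted samples is a candidate source, although the CD4 and Foxp3-GFP gate would remove these cells. The deviations of the 4 genes from their group means followed those of the 25 macrophage and dendritic cell markers over the 12 libraries, with r = 0.714 (permutation p = 0.0309), rho = 0.622 (permutation p = 0.0738) and r = 0.602 without ST2-negative arginine replicate 1 and ST2-positive untreated replicate 2. The list had medians of -0.647 and -0.368, smaller changes that exclude nothing, since the 4 genes were picked for their fall and the list holds members with a high level. Cd74 and C1qb, abundant in such cells, were at 730 and 66.7 CPM in ST2-negative cells of untreated mice, 0 of the list's members are in another list, and a change with arginine within macrophages or within Tregs stays open.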

How the results depend on the processing

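The covariate for the no-feature share was chosen only after the data had been seen, and so were the leave-one-out tests of 4 lists. Of the values of named genes under an alternative, 4451 kept their direction and their side of the threshold, 531 kept their direction and no longer passed, 12 passed newly and 58 turned sign, all 58 without a call. For lists these numbers were 607, 99, 32 and 6, and 115 of 225 counts stayed within 1.5 times. The covariate ended 78 calls of named genes, limma voom 13 and a fit on only the 6 libraries compared 12, and an estimated correlation ended 56 list calls and fry 34, while 9 lists passed newly with fry. With the covariate 9 lists lost a call and 16 gained one without a change of direction, and 6 others that passed before or after turned. DESeq2 size factors ended 5 named calls and turned no called gene. Of 109, 95, 66, 38 and 6 named genes that passed in the 5 comparisons, 92, 67, 28, 14 and 0 passed without each library in turn. Depth sets a floor, since under 0.566 to 1.03 CPM a gene had fewer than 3 counts. Of genes changed 2-fold in counts simulated at the depth, dispersion and number of these libraries, 64.2% to 37.3% were recovered. Far fewer genes were changed there than were called between the gates, which also affects these shares. Which of these settings limits recovery was not tested. The cause was not tested for any change below, except that fewer libraries or fewer tested genes are part of the alternatives that leave out libraries or filter.

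Counts of genes past the threshold moved by over 1.5 times as follows. With the covariate the count was 662 (443 higher, 219 lower) between the gates of untreated mice, 185 (55 lower) with arginine in ST2-negative cells, 168 (93 higher, 75 lower) with it in ST2-positive cells and 0 (0 higher, 0 lower) in the interaction by edgeR, with 932 genes at an unadjusted p under 0.05, while DESeq2 and limma voom without the covariate gave 49 and 46. Without a filter it was 535 (317 lower) and 269 (142 higher, 127 lower) with arginine in ST2-negative and ST2-positive cells and 122 (82 higher, 40 lower) in the interaction. With DESeq2 these were 509 (304 lower), 196 (131 higher) and 49 (43 higher, 6 lower). With limma voom the count was 767 (345 higher, 422 lower) in ST2-negative cells and 46 (36 higher, 10 lower) in the interaction. On only the 6 libraries compared 279 genes were lower between the gates of arginine-treated mice, and 606 (283 higher, 323 lower) changed with arginine in ST2-negative cells. At 5 CPM in 3 libraries 82 were higher with arginine in ST2-positive cells. The labels do not say whether libraries with the same replicate number share mice. In their deviations from the group means, same-numbered libraries of the 2 gates correlated at 0.0313 to 0.273, in 4 of 6 cases best with their own number, and those of the 2 treatments at -0.207 to 0.0369, in 1 of 6 cases. Not every correlation passed the limit of 0.1 set for pairing, so the main fits did not use the numbers as pairs. The rule for naming interaction genes did use them. A block on the numbers gave 39 genes (25 higher, 14 lower) in the interaction. Without 1 library at a time the counts ranged from 1594 to 3147 (729 to 1506 higher, 865 to 1641 lower) and from 638 to 747 (348 to 505 higher, 242 to 361 lower) between the gates of untreated and arginine-treated mice. With arginine they ranged from 93 to 712 (38 to 320 higher, 47 to 392 lower) in ST2-negative and from 25 to 126 (10 to 81 higher, 15 to 45 lower) in ST2-positive cells, and in the interaction from 0 to 62 (0 to 44 higher, 0 to 18 lower).

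Signs turned in these values (log2), none of them a call. Cd4 between the gates of untreated mice was at 0.0954 with the covariate. Slc7a1 between the gates of untreated mice was at 0.0186 with the covariate. Cd4 between the gates of arginine-treated mice was at 0.0269 with DESeq2 size factors, 0.0144 without a filter, 0.0407 at 5 CPM in 3 libraries, 0.00916 with DESeq2, 0.0379 with limma voom, 0.0516 on the 6 libraries compared, 0.0013 with the replicate block and 0.0679 with the covariate. Slc7a1 between the gates of arginine-treated mice was at 0.0186 with DESeq2 size factors, 0.00715 without a filter, 0.0309 at 5 CPM in 3 libraries, 0.00242 with DESeq2, 0.000746 with limma voom, 0.0414 on the 6 libraries compared and 0.0502 with the covariate. Il2ra with arginine in ST2-negative cells was at -0.0115 with DESeq2 size factors, -0.0419 without a filter, -0.024 with DESeq2 and -0.0555 with limma voom. Odc1 with arginine in ST2-negative cells was at -0.00441 with DESeq2 size factors, -0.0352 without a filter, -0.0174 with DESeq2 and -0.0179 with limma voom. Cd4 with arginine in ST2-negative cells was at 0.0648 with the covariate. Arg1 in the interaction was at 0.379 with limma voom. Cd4 in the interaction was at -0.0274 with the covariate. Pparg in the interaction was at -0.0349 with the covariate.

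Without 1 library at a time, between the gates of arginine-treated mice, values ranged for Arg1 from -0.232 to 0.844, Cd4 from -0.0279 to 0.0793 and Slc7a1 from -0.112 to 0.113. Without 1 library at a time, between the gates of untreated mice, values ranged for Arg1 from -0.00479 to 0.3997. Without 1 library at a time, with arginine in ST2-negative cells, values ranged for Il2ra from -0.113 to 0.0282 and Odc1 from -0.0678 to 0.0246. Without 1 library at a time, with arginine in ST2-positive cells, values ranged for Cd4 from -0.00214 to 0.168, Foxp3 from -0.00673 to 0.16, Gata3 from -0.01998 to 0.108 and Ptprc from -0.0146 to 0.0972. Without 1 library at a time, in the interaction, values ranged for Arg1 from -0.432 to 0.65, Gata3 from -0.151 to 0.0233, Il2ra from -0.201 to 0.00263, Pparg from -0.0143 to 0.343 and Ptprc from -0.114 to 0.00633. With the covariate camera turned the direction of 6 list results: the mesothelium and stroma list between the gates of untreated mice, with arginine in ST2-negative cells and in the interaction (adjusted p = 0.0364, 0.0173 and 0.0056), the T cell receptor list with arginine in ST2-negative cells and in the interaction (0.0188 and 0.796), and the Treg identity list in the interaction (0.022).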

Other observations

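Every test named here with a p comes from the models described for the report, and the pancreas and immunoglobulin genes were chosen only after their values were seen.

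Further groups of genes separated the gates in arginine-treated mice. Interferon response genes were higher in ST2-positive cells in 5 of 35 cases (8 adjusted over the list alone), among them Igtp at 0.68 and Gbp2 at 0.60 (log2, SE 0.0858 and 0.111). Camera gave an adjusted p of 0.000521, and 0.354 with an estimated correlation. Immediate-early and heat-shock genes were higher in 10 of 31 cases, among them Atf3 at 1.39 and Nr4a1 at 0.75 (SE 0.171 and 0.0872), and lower in 4 (14 and 5 adjusted over the list alone, adjusted p = 0.00109, and 0.28 with an estimated correlation). T cell receptor genes were lower in 6 of 20 cases, among them Trbc1, Trbc2 and the kinase gene Zap70 (7 adjusted over the list alone, adjusted p = 0.000685, and 0.331 with an estimated correlation). Th1-associated genes were lower in 5 of 13 cases, among them Ccl5 at -1.77 and Tbx21 at -1.10 (SE 0.122 and 0.134), and higher in 3, and that list passed as lower with fry but not with camera (5 each way adjusted over the list alone, adjusted p = 0.0135 and 0.134).

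With arginine, genes of the visceral adipose tissue list went both ways in ST2-negative cells, with 5 of 22 higher, among them Dgat2 and Ccr2, and 3 lower, among them Il10 (7 and 6 adjusted over the list alone, adjusted p = 0.344). The number higher was 3 without arginine replicate 1 or untreated replicates 2 or 3, and the number lower 1 without arginine replicate 3 or untreated replicate 2 and 5 without arginine replicate 2. With the no-feature share as a covariate the list passed as higher with the preset correlation (adjusted p = 0.0135). In ST2-positive cells 3 were higher and 2 lower, Il10 and Cxcl2 (6 and 3 adjusted over the list alone), with a median of 0.02, a mean of -0.02 and a test of the median's sign (adjusted p = 0.309). By edgeR 0 were higher without arginine replicate 2 or untreated replicate 2, and 1 without arginine replicate 1 or untreated replicate 3. Oxidative phosphorylation genes had a median of -0.19 in ST2-negative cells with 0 of 76 past the edgeR threshold over all genes or over the list alone (camera adjusted p = 6.13e-12, and 0.332 with an estimated correlation).

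Genes of the exocrine pancreas stood out in ST2-positive untreated replicate 2. All 21 of those with at least 20 counts were highest in it, and their list summed to 719.9 CPM there and to 21.0 to 81.7 CPM in the other libraries. Pnlip, which encodes pancreatic lipase, was at 106.5 CPM in it and at most 2.99 CPM elsewhere. Single libraries also stood out in immunoglobulin genes: Ighg3 was at 960.2 CPM in the same library, and Igha at 263.6 and 164.2 CPM in ST2-negative untreated replicates 2 and 3. Immunoglobulin constant and secretory genes together took 982.6 to 4726 CPM. All CPM in this paragraph are scaled to the total counts in genes of a library, without the TMM factors.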
